A study of Homo sapiens with 4 samples.

How the data were processed

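Total RNA from 4 human germ cell tumour cell lines, 1 per tumour subtype, was prepared with a column kit, labelled with biotin and hybridized by the authors to Affymetrix U133 Plus arrays with 54675 probe sets, 1 array per line. The groups follow the labels: TCam-2 for seminoma, NT2D1 for teratoma, GCT27 for embryonal carcinoma and GCT44 for yolk sac tumour. All cultures held serum, but the medium was RPMI for the seminoma line and DMEM for the other 3 lines. The deposited values are intensity values on a linear scale, 1 per probe set and array, with a highest value of 46375, 42717, 41955 and 55282 for the 4 lines in that order. After trimming 2% from each end, their mean was 500.1 on every array. The authors' processing notes name RMA without a version, a method that gives log2 values, so the values on hand are not its usual output. They were therefore treated as linear and scaled, and log2 was taken here.

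Probe sets were assigned to genes from the array annotation. 41097 probe sets were listed with a single gene symbol, 1801 with several and 11777 were not listed. Each gene was represented by its single-gene probe set with the highest mean over the 4 arrays, which gave 19775 genes. A gene was compared when its highest value reached 76.4 units, the median of all values, which left 14926 genes. Values below 76.4 were set to it for fold differences, because low intensities are not ordered on such arrays. This floor was chosen after the values were seen, since the values were not on the log2 scale that had been assumed. The share of probe sets above the floor was recorded, which is near 50% by construction and does not measure signal over background. The number of arrays limits the precision. The files name no genome build, so no coordinates are given, and gene order was taken from the current reference gene table only for a test of neighbouring genes.

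A gene was called higher or lower in a line when its log2 value lay at least 2 (4-fold) beyond the nearest of the other 3 lines. This rule of size has no error rate, because no line has replicates. Pairs of lines were compared with the same threshold, and Pearson and Spearman correlations were computed across genes. limma (version 3.58.1, with R 4.3.3) was fitted to log2 values without the floor, with an intensity trend, for the seminoma line against the 3 non-seminoma lines. It has 2 residual degrees of freedom, which come from lines of different subtypes, and it assumes that the lone line varies as those do. P-values were adjusted by the Benjamini-Hochberg method over 14926 genes and, for fixed lists, over the list alone.

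18 gene lists were written before the data were examined: germ cell and seminoma genes, embryonal carcinoma and primed pluripotency genes, shared pluripotency genes, yolk sac and visceral endoderm genes, neural and ectoderm genes, mesoderm and mesenchyme genes, trophoblast genes, cancer-testis genes, DNA methylation machinery, imprinted genes, genes known as methylation targets in tumours, p53 targets and apoptosis genes, DNA repair genes, antigen presentation genes, BMP pathway genes, WNT pathway genes, blood cell genes and housekeeping genes. Of 402 entries 305 were compared, 37 were below the filter and 60 had no probe set assigned to that gene alone and were not analysed here. For each list and line, the median difference between the line and the mean of the other 3 was placed among 10000 random lists matched on mean expression in 20 bins (seed 1). Medians outside the central 95% are described as above or below the random lists.

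The comparisons, the lists and the rule for naming genes were fixed before the data were examined. The rule named the 12 widest margins each way for the seminoma line, 6 each way for the other lines and for the teratoma line against the embryonal carcinoma line. From each list it named up to 4 members per comparison and the first 2, and it left out uncharacterised loci and sex-linked marker genes. The alternatives fixed beforehand were the median over the probe sets of a gene, leaving out probe sets that match several transcripts (suffixes _s_at and _x_at), no filter, a stricter filter at the 70th percentile (252 units), arrays centred on the median, a threshold of 1, the mean of the other lines as reference, limma without a trend or with robust estimation, and leaving out each line. No floor, a floor at the unspiked controls (30.1 units), quantile normalization, scaling to the spiked-in hybridization controls, and limma on floored values or on values plus the floor were chosen after the values were seen. The procedure was tested on simulated data with 200 changed genes among 14926. The size rule recovered 37 of 50 genes raised by 3 on the log2 scale, 49 of 50 raised by 5, 22 of 50 lowered by 3 and 21 of 50 lowered by 5, while limma recovered 0 of the 200. Of the genes lowered by 3 and by 5, only 25 and 9 were counted as bright enough to show the fall. The size rule recovered 20 and 8 of these. Other work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.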

Results

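Gene expression was measured in 4 established human germ cell tumour cell lines, each on 1 single-colour oligonucleotide array. TCam-2 represents seminoma, NT2D1 teratoma, GCT27 embryonal carcinoma and GCT44 yolk sac tumour, as the labels name the subtypes. NT2D1 is widely used as a pluripotent embryonal carcinoma line, so values of the teratoma line stand for that line under its label and not for differentiated teratoma tissue. The study set the seminoma line against the 3 non-seminoma lines to find genes silenced in the latter, and its DNA methylation arrays of the lines are not used here. No line has a replicate, so no difference below carries a replicate error, and the number of arrays limits the precision. The seminoma line was grown in RPMI medium and the other 3 in DMEM, so medium and subtype cannot be told apart in any comparison of that line. The 4 arrays had similar median intensities of 73.6 in TCam-2, 77.4 in NT2D1, 79.3 in GCT27 and 75.4 in GCT44. Between 49.2% and 50.9% of the 54675 probe sets lay above 76.4 units, the median of all values, which served as the floor below which levels were not ordered. The yolk sac tumour array differed in some of its controls. Its 3'/5' signal ratio for ACTB was 4.21 against 2.49 to 2.97 on the others, while that for GAPDH was 1.04 and lay within the 0.90 to 1.09 of the others. Its spiked-in hybridization controls lay 0.29 above their mean on the log2 scale, against -0.25 for GCT27 and about -0.03 for TCam-2.

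A gene was called higher or lower in a line when it lay at least 4-fold beyond the nearest of the other 3 lines. Among 14926 genes compared, 222 were higher and 111 lower in the seminoma line, 78 and 36 in the teratoma line, 90 and 48 in the embryonal carcinoma line, and 253 and 252 in the yolk sac tumour line. Where a value lay at the floor the fold is a lower bound and is written "at least". With the median over the probe sets of a gene, 65 genes were lower in the seminoma line, 51 higher in the teratoma line, 23 lower in the embryonal carcinoma line and 133 lower in the yolk sac tumour line, so these counts depend on the choice of probe set. All counts are a rule of size and not a test. In simulated arrays with the gene-wise spread of the 3 non-seminoma lines, the rule called 231 of 14726 unchanged genes in the seminoma line.

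**Figure D1:**
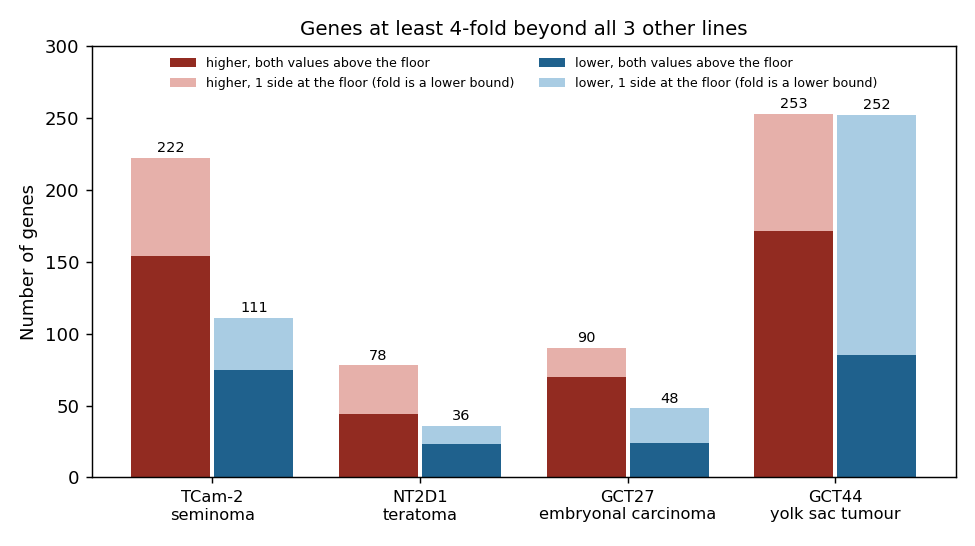
Number of genes at least 4-fold higher (red) or lower (blue) in each line than in all 3 others, with 1 array per line, where pale parts are genes with 1 side at the floor. GCT44 has 253 and 252 such genes and TCam-2 has 222 and 111, against 78 and 36 in NT2D1.

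The first comparison asks which genes distinguish the seminoma line from the non-seminoma lines. PRAME, a cancer-testis antigen that represses retinoic acid signalling, had the widest margin on floored values. Its intensity was 9713 in TCam-2 against 79.5 in the next line, a 122-fold difference. SOX17, a transcription factor of endoderm and of the human germ line, reached 3819 and was at least 50-fold higher than elsewhere. CGA, the common alpha subunit of the glycoprotein hormones, was at least 60.5-fold higher. Further genes were the glutathione transferase GSTA3 (at least 79.2-fold), the long non-coding RNA UCA1 (at least 64.7-fold), the BMP and WNT antagonist SOSTDC1 (62.7-fold), IGF1 (51.6-fold) and the prolactin receptor PRLR (at least 44.3-fold). The cannabinoid receptor CNR1 (at least 40.9-fold), the IGF-binding protein IGFBP3 (36.6-fold), the glutathione peroxidase GPX2 (32.5-fold) and SMAGP (29.3-fold) completed the 12 widest margins. The margin of CNR1 was 1.38 on the log2 scale, short of the size rule, when the median over its probe sets was taken.

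Of the genes lower in the seminoma line, the zinc finger gene ZIC2 had an intensity of 3.10 in TCam-2 and between 8268 and 11603 in the other lines, at least 108-fold lower. TMCO1, a calcium channel of the endoplasmic reticulum, was at least 87.7-fold lower, and its 3 other informative probe sets were also lower there, each by at least 1 on the log2 scale. The chromatin gene CECR2 was at least 54.5-fold lower, BEX1 at least 45.9-fold, and GPX1, an abundant glutathione peroxidase, 32.2-fold lower at 126 units. SALL1, a zinc finger transcription factor, was 32.0-fold lower, HDHD5 at least 27.7-fold, the pseudogene DUXAP10 22.0-fold, and the antiviral membrane protein BST2 at least 21.2-fold. The histone deubiquitinase MYSM1 was at least 21.8-fold lower, FAT3 at least 20.1-fold and TMEM47 at least 17.1-fold. The call of MYSM1 was lost with the median over its probe sets, where its margin was 0.00, and that of DUXAP10 was lost without probe sets that match several transcripts, where its margin was -0.64. ZIC2, BEX1, GPX1, HDHD5 and BST2 had no other probe set. DUXAP10, MYSM1 and TMEM47 had none bright enough in the other lines to show a 4-fold fall.

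Among the fixed lists, germ cell and seminoma genes were higher in TCam-2 for 7 of 20 members compared, lower for 0, and within the size rule for 13. Besides PRAME and SOX17, these were the chemokine receptor CXCR4 (11729 units, 26.7-fold), TCL1A (at least 21.1-fold) and the transcription factor TFAP2C (20557 units, 8.42-fold), with 2 further members at smaller margins. PRDM1, a regulator of germ cell specification, had 2481 units in TCam-2 and 1550 in GCT44, and did not meet the rule. The median difference of the list from the mean of the other lines was 2.24 on the log2 scale, above all 10000 random lists matched on expression. Trophoblast genes were higher for 6 of 14 members, with a median of 1.92, also above all random lists. Among them were CGA, the keratin KRT7 (at least 19.3-fold), the placental envelope gene ERVFRD-1 (at least 11.5-fold), and the transcription factors TFAP2A (5.88-fold) and GCM1 (at least 5.36-fold).

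Further lists lay below the random lists in the seminoma line, and in all but the cancer-testis list no member met the size rule. The 17 embryonal carcinoma and primed pluripotency genes had a median of -1.35. SOX2 had 391 units in TCam-2 against 20575 in NT2D1, 18309 in GCT27 and 6.41, below the floor, in GCT44. DNMT3B had 2841 against 11360, 23760 and 2377 in that order. Without the embryonal carcinoma line the list median was -0.33, within the random range. The 14 neural and ectoderm genes had a median of -1.24. NES had 439 units in TCam-2 against 2259 in NT2D1, 1715 in GCT27 and 252 in GCT44. PAX6 had 62.8 against 85.3, 56.5 and 31.4 in that order, of which only 85.3 lay above the floor. The 22 yolk sac and visceral endoderm genes had a median of -0.70, which was 0.00 without the yolk sac tumour line. AFP at 66.9 units and GATA4 at 70.5 lay below the floor in TCam-2, and GATA4 did so in NT2D1 and GCT27 too. The 18 WNT pathway genes had a median of -0.59, which was -0.20 and within the random range without the yolk sac tumour line. For the 19 cancer-testis genes a median of -0.32 lay at the 1.33 percentile although 2 members were higher, XAGE2 (19.5-fold) and the helicase gene DDX43 (at least 15.4-fold). That median was -0.16 without the embryonal carcinoma line and 0.00 without the yolk sac tumour line. It was -0.13 with no filter on low values and -0.27 with arrays centred on the median. Each of these lay within the random range. PRAME, itself a cancer-testis antigen, was placed in the germ cell list alone and is not counted among these genes.

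The remaining lists had medians inside the central 95% of random lists in the seminoma line. Of 16 genes of the DNA methylation machinery 1 was higher, DNMT3L, the catalytically inactive partner of the de novo methyltransferases (2083 units, 11-fold), while DNMT1 had 2171 units and DNMT3A 3339, and the list median was 0.13. Among 14 pluripotency genes shared by germ cell tumours, with a median of -0.17 but a mean of 0.64, KLF5 was higher (6.54-fold), and NANOG (22390 units) and LIN28A (14828 units) were not set apart. Of 20 mesoderm and mesenchyme genes, with a median of -0.11 and a mean of 0.04, the matrix genes LUM (13.9-fold) and COL3A1 (11-fold) were higher and COL1A1 was lower (5.03-fold). Of 16 antigen presentation genes, with a median of -0.36, B2M, the invariant chain of class I molecules, was 6.98-fold lower at 1309 units against 9138 to 16893, and HLA-B had 680 units against 602 to 1522. None of the 21 imprinted genes (median 0.09), 20 genes known as methylation targets in tumours (0.16), 19 p53 targets and apoptosis genes (0.08), 15 DNA repair genes (-0.15, mean 0.05), 20 BMP pathway genes (-0.35) or 9 blood cell genes (-0.19) met the size rule. First members of these lists had intensities in TCam-2 of 3529 for IGF2R, 12670 for PEG3, 238 for RASSF1, 831 for MGMT, 11605 for MDM2, 568 for ERCC1, 222 for BMP4 and 61.4 for CD3E. The 11 housekeeping genes had a median of 0.06 and a mean of -0.38, with B2M as the only lower member, ACTB at 29002 units and GAPDH at 28043.

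**Figure D2:**
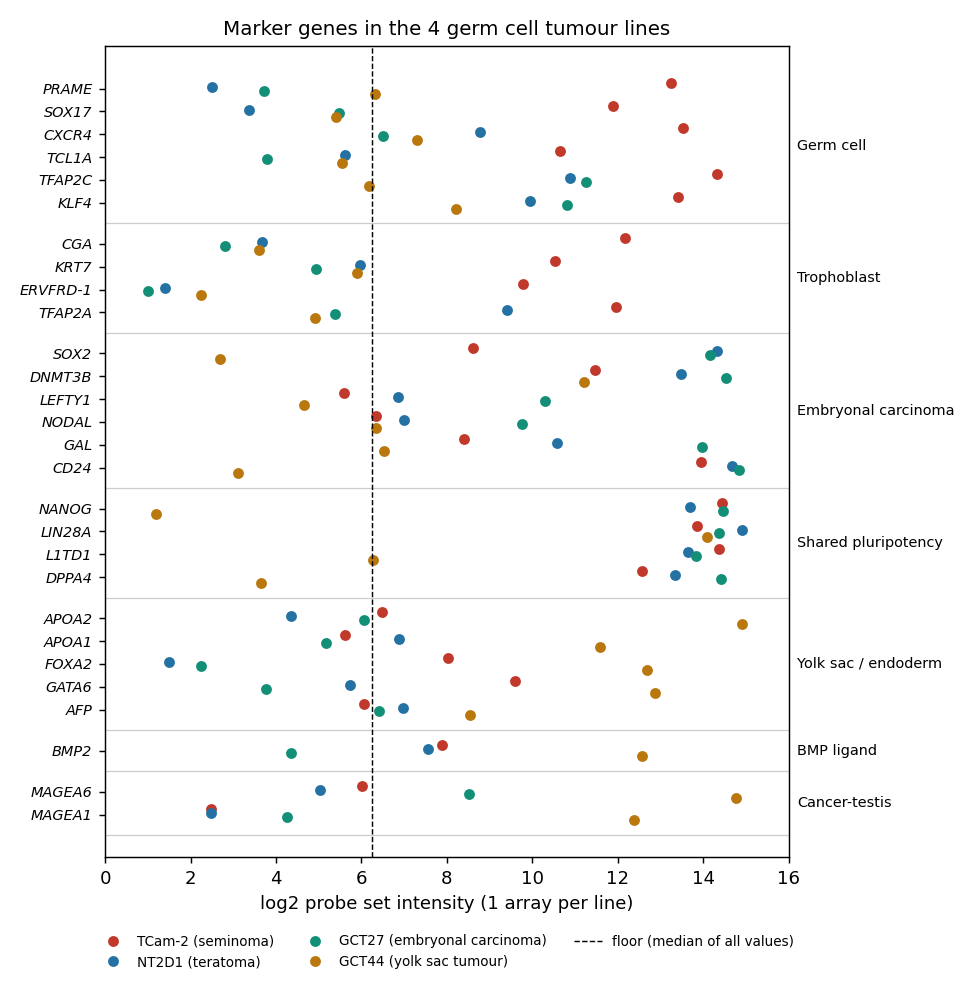
Intensity of marker genes on a log2 axis, with 1 point per cell line, no replicates, and a dashed line at the floor of 76.4 units. TCam-2 lies highest for PRAME at 9713 units, and GCT44 lies lowest for NANOG at 2.29 units and highest for APOA2 at 30689 units.

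The contrast of 1 seminoma against 3 non-seminoma lines was also tested with limma, in which the spread comes from 3 lines of different subtypes and the lone line is assumed to vary alike. No gene of 14926 passed an adjusted p of 0.05. Counts at an unadjusted p are not read here. Over the 4 ways of setting 1 line against 3 they lay both above and below the number expected by chance. ZIC2 came closest, with a log2 difference of -11.66 (SE 0.51) and an adjusted p of 0.065, followed by TMCO1 at -10.29 (SE 0.65) and an adjusted p of 0.196. These differences use TCam-2 values far below the floor, so their size is not measured, and with floored values the smallest adjusted p in limma was 0.0522 for another gene, ABCA13. ZIC2 was the only gene called under 4 of 14 alternatives, and no gene was called under the other 10. It has a single probe set here, and its log2 difference was -11.7 under each of these 4. They left its own values nearly unchanged, so they add no independent evidence for it. Adjusted over the list alone, SOX17, TCL1A, PRAME and CXCR4 passed among germ cell genes (each with an adjusted p of 0.0183). Adjusted over the list alone, CGA (0.00701) and KRT7 (0.0123) passed among trophoblast genes, COL1A1, COL3A1 and LUM (each 0.0473) among mesoderm genes, and B2M among antigen presentation (0.0184) and housekeeping genes (0.0126). None of them passed over all genes in limma, and the calls over the list alone rest on the assumed spread of a lone array. These fits used values without the floor. All 3 other lines lay below the floor for CGA, KRT7, SOX17 and TCL1A, and some did for PRAME, COL3A1 and LUM. The sizes and spreads behind those calls are therefore not measured.

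The yolk sac tumour line was compared in the same way with the other 3. APOA2, an apolipoprotein of liver and yolk sac, had 30689 units in GCT44 and 89.2 in the next line, a 344-fold difference. The neuropeptide gene GRP was at least 173-fold higher, the receptor tyrosine kinase ERBB4 at least 124-fold, and LHX1, a transcription factor of early endoderm and kidney, at least 58.5-fold. MAGEA6 (76.1-fold) and MAGEA1 (at least 69.5-fold) belong to a family of near-identical genes and are uncertain as to which member gave the signal. Of the genes lower there, NANOG, a core pluripotency factor, had 2.29 units against 13322 to 22428, at least 174-fold lower, and the stem cell gene L1TD1 was 164-fold lower. The surface proteins CD9 (at least 216-fold) and CD24 (at least 207-fold), the ubiquitin-conjugating enzyme UBE2C (at least 119-fold) and POU5F1B (at least 186-fold), whose probe set can detect near-identical copies, were also lower. UBE2C and POU5F1B had no other probe set, and CD9 had none bright enough in the other lines to show a 4-fold fall. Failure of the probe set used was therefore not checked for these genes. The margin of ERBB4 was 1.53, short of the rule, with the median over its probe sets. On this array the ACTB 3'/5' ratio was the highest of the 4 but the GAPDH ratio was not. Scaling to the spiked-in controls changed the split of 253 higher and 252 lower genes to 180 and 306. Centring the arrays on the median changed it the other way, to 299 and 221.

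Of 22 yolk sac and visceral endoderm genes, 8 were higher in GCT44 and 0 lower, with a median of 1.07, above all random lists. Besides APOA2 these included APOA1 (26.0-fold), the pioneer factor FOXA2 (25.6-fold) and FGG (at least 23.2-fold), with 4 further members at smaller margins. AFP, the serum marker of yolk sac tumour, had 372 units against at most 126, and GATA4 had 104. Of 20 BMP pathway genes 3 were higher (median 0.87), the ligands BMP2 (25.8-fold) and BMP5 (at least 7.27-fold) and the target gene MSX1 (5.42-fold). Of 20 mesoderm genes EOMES (26237 units, 14.0-fold) and FN1 (7.11-fold) were higher, with a list median of 0.33 at the 98.5 percentile, or -0.02 when scaled to the spiked-in controls. That scaling moved the median of all genes to -0.31, and the list still lay at the 98.9 percentile. The list median lay within the random range at 0.04 with the median over probe sets and at 0.13 without the seminoma line, 0.14 without the teratoma line and 0.28 without the embryonal carcinoma line. Among 19 cancer-testis genes 5 were higher, MAGEA6, MAGEA1, MAGEA12 (55.9-fold) and CTAG2 (at least 14.5-fold) among them, while the list median was -0.20 inside the random range and the mean 1.12. Of 18 WNT pathway genes 3 were higher, the antagonist DKK1 (8.93-fold), SP5 (6.18-fold) and the receptor LGR5 (5.77-fold), with a median of -0.24 inside the random range and a mean of 0.23.

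The germ cell list in GCT44 held 3 lower members of 20, TFAP2C (at least 24.9-fold), PDPN (at least 23.4-fold) and PRDM14 (at least 6.19-fold), with a median of -1.55. The mean behind that median includes TCam-2, where the list itself had a median of 2.24. The value of -1.55 therefore does not measure a fall against NT2D1 and GCT27 alone. Embryonal carcinoma genes were lower for 4 of 17 members, among them CD24, the deubiquitinase USP44 (at least 7.05-fold), SOX2 (at least 5.12-fold) and FGF4 (at least 4.50-fold), with a median of -2.49. Of 14 shared pluripotency genes NANOG, L1TD1 and DPPA4 (at least 79.6-fold) were lower, while LIN28A had 17340 units. The median of that list was -0.61, at the 0.080 percentile. The median of 16 antigen presentation genes was -0.66 with no member meeting the rule, HLA-B having 602 units and HLA-C 753, while B2M had 16893. Of 20 genes known as methylation targets TSPYL5 was higher (4.76-fold) and CDH1, which encodes E-cadherin, and CXCL12 were lower (at least 7.59-fold and at least 10.7-fold). Imprinted genes had 3 lower members of 21, PHLDA2 (at least 19.3-fold), ZDBF2 (at least 16-fold) and CDKN1C (at least 4.22-fold). The T cell gene CD3D was the only higher member of 9 blood cell genes, with 2803 units and a 17.4-fold margin, while CD3E had 88.4 units. The death receptor TNFRSF10A was at least 10.4-fold lower among p53 targets, and FABP7 was 5.11-fold higher among neural genes. Housekeeping genes had a median of 0.56 in GCT44, or 0.16 when scaled to the spiked-in controls and 0.76 when arrays were centred, above the random lists in each. It lay within the random range at 0.39 with the median over probe sets and at 0.41 without the seminoma line. This list was written as a control. Its median gives no calibrated threshold for other lists or for negative medians. Positive list medians in GCT44 of at most 0.56, such as 0.33 for mesoderm genes, were not larger than that of the control.

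The embryonal carcinoma line was set against the other 3 next. HORMAD1, a meiotic chromosome axis gene, had 5949 units in GCT27 and was at least 77.8-fold higher than in any other line. The non-coding RNAs LINC02582 (at least 56.4-fold), ARGLU1-DT (43.5-fold) and VHRT (41.3-fold), the matrix protein EDIL3 (24.9-fold) and the endothelin receptor EDNRB (20.5-fold) followed. Lower genes were the zinc finger gene ZNF22 (30.3-fold), cytochrome b5 CYB5A (at least 28.7-fold), the WNT secretion factor WLS (24.5-fold), NUDT19 (at least 17.4-fold), ASAP2 (at least 12.1-fold) and the histamine methyltransferase HNMT (at least 11.5-fold). With the median over probe sets the margin of EDIL3 was 1.66 and that of HNMT 0.00, and HNMT was also lost without probe sets matching several transcripts. Scaling to the spiked-in controls moved the split of 90 higher and 48 lower genes to 147 and 38. Centring the arrays on the median moved it the other way, to 77 and 53.

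Embryonal carcinoma and primed pluripotency genes had a median of 3.2 in GCT27, above all random lists, and 4 of 17 members were higher. These were the Nodal pathway genes LEFTY1 (10.9-fold) and NODAL (6.73-fold), the neuropeptide GAL (10.4-fold) and the chromatin gene JARID2 (4.31-fold). Shared pluripotency genes had a median of 0.96 with 0 of 14 set apart, NANOG being at 22428 units. BMP pathway genes had a median of -1.37, below all random lists, with ID2, a BMP target, 10.5-fold lower and BMP2 at 20.6 units. Antigen presentation genes had a median of 0.97 and 1 of 16 members higher, the immunoproteasome subunit PSMB8 (at least 4.40-fold). Trophoblast genes had a median of -1.15 with GATA3 lower (6.39-fold), and that median was -0.02 without the seminoma line. The median of p53 targets and apoptosis genes was 0.53, and 0.36 and just inside the random range with the median over probe sets. Endoderm genes had a median of -0.33, which was 0.00 without the yolk sac tumour line. With arrays centred on the median it was -0.41, at the 4.83 percentile and so within the random range. The methylcytosine dioxygenase TET2 was at least 4.45-fold lower, and of 21 imprinted genes NAP1L5 was at least 10.1-fold lower.

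In the teratoma line the neuronal microtubule gene MAP2 had 5939.8 units against 78.2 in the next line, a 75.9-fold difference. PNMA2 (28.8-fold), the cardiac myosin gene MYH6 (at least 22.0-fold), the metalloprotease PAPPA (19.6-fold), the adipokine RARRES2 (18.7-fold) and the piRNA pathway gene PIWIL2 (at least 18-fold) were also higher. EID1 was at least 56.9-fold lower, the hypoxia-inducible factor EPAS1 21.1-fold, the collagen gene COL1A2 at least 17.6-fold, catalase CAT at least 15.5-fold, FGF13 12.4-fold and the galectin LGALS1 11.9-fold. With the median over probe sets PAPPA (1.16), EPAS1 (0.00) and CAT (-1.46) fell short of the rule, and COL1A2 (-0.17) did so without probe sets matching several transcripts. Neural and ectoderm genes had a median of 0.91, above all random lists, with MAP2 and the transcription factor SOX11 (6.16-fold) higher among 14. The WNT transcription factor LEF1 (at least 6.83-fold) and the BMP antagonist GREM1 (5.53-fold) were the only higher members of their lists.

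Embryonal carcinoma and primed pluripotency genes had a median of 1.34 in NT2D1 with 0 of 17 members set apart, SOX2 lying at 20575 units. Imprinted genes had a median of 0.50, which was 0.07 without the embryonal carcinoma line. Further medians in NT2D1 lay below the random lists, with -0.38 for germ cell genes, -0.58 for endoderm genes, -0.55 for trophoblast genes, -0.45 for cancer-testis genes and -0.37 for p53 targets. The first and the trophoblast median were -0.03 and 0.00 without the seminoma line. The endoderm and cancer-testis medians were 0.00 and -0.07 without the yolk sac tumour line. The p53 median was -0.19 without the embryonal carcinoma line and -0.28 with the median over probe sets. All of these lay within the random range. The germ cell median also lay within it when quantile normalized (-0.37) and when scaled to the spiked-in controls (-0.34).

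**Figure D3:**
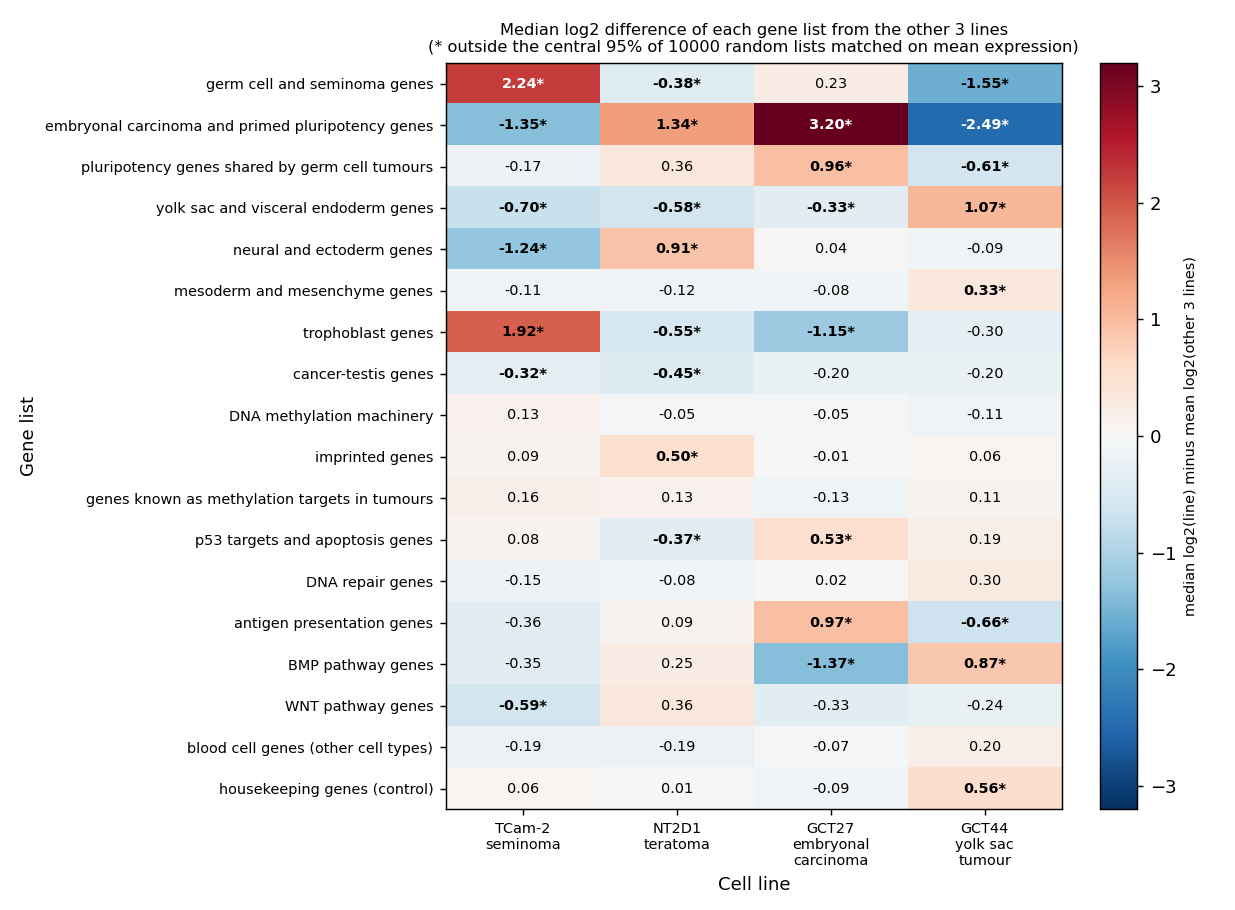
Median over each gene list of the log2 difference between a line (columns) and the mean of the other 3 lines, with red for higher, blue for lower and an asterisk for medians outside the central 95% of 10000 random lists matched on mean expression. Germ cell genes stand at 2.24 in TCam-2 and embryonal carcinoma genes at 3.2 in GCT27.

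The lines were last compared in pairs. NT2D1 and GCT27 were the most alike, with 697 genes at least 4-fold apart and a Pearson correlation of 0.911 across genes, which are not independent replicates. TCam-2 differed by 1233 genes from NT2D1 and 1100 from GCT27, and GCT44 differed by 1505 genes from TCam-2, 1273 from NT2D1 and 1411 from GCT27. The correlations of the other 5 pairs ran from 0.831 to 0.877. Higher in NT2D1 than in GCT27 were the MAP kinase phosphatase DUSP6 (at least 83.4-fold), MAP2 (at least 77.7-fold), WLS (42.9-fold), GAS1 (36.1-fold), SP8 (32.4-fold) and RPL39L (at least 31.1-fold). Lower were the non-coding RNA LINC00458 (at least 366-fold), EDNRB (133-fold), HORMAD1 (at least 77.8-fold), EID1 (at least 62.5-fold), LINC02582 (at least 56.4-fold) and VHRT (55.5-fold). LINC00458 was also abundant in GCT44, at 24943 units. The pair of NT2D1 and GCT27 counted 457 genes with the median over probe sets.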

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

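The tests of neighbouring genes were chosen after the result was seen, and their form replaced a narrower one. Of 11721 probe sets with no gene assignment, which no comparison above used, 5328 reached the floor. They were flagged only because they lie outside the genes compared. Of the 5328, 41 were at least 4-fold beyond the other lines in the seminoma line, 16 in the teratoma line, 27 in the embryonal carcinoma line and 82 in the yolk sac tumour line. Among the 14926 genes compared the share set apart was 2.23%, 0.76%, 0.92% and 3.38% in that order. The share of the 5328 was lower in each line, though genes were read by their brightest probe set. In the seminoma line 26 of the 41 were higher, and the widest margin was 17565 units against 92.1 in the next line. The yolk sac tumour line had 60 higher and 22 lower. No explanation of these signals was tested.

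The yolk sac tumour line had the most genes set apart, 505 against 333 in the seminoma line. Scaling the arrays to the spiked-in controls left 486 genes against 327 in the next line, which argues against array scaling as the whole cause. Counting only genes above the floor on both sides gave 256 against 229, too close to tell noise at low signal from a difference of the line. RNA quality was not tested as a cause: the ACTB 3'/5' ratio was highest on that array at 4.21, while the GAPDH ratio of 1.04 lay within the 0.90 to 1.09 of the others. A difference of subtype may contribute and was not tested, because each subtype has 1 line.

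Genes next to each other on a chromosome were set apart together more often than in 95% of 10000 random gene sets for 5 of the 8 sets of higher or lower genes, but not for the teratoma line (2 and 0 pairs) or for genes lower in the embryonal carcinoma line (1 pair). For genes higher in the seminoma line there were 16 neighbouring pairs (random median 3), and 11 after related or overlapping genes were removed (random median 2, 95th percentile 5). Shared signal between related genes is therefore not the whole cause in that set. For genes lower in the yolk sac tumour line 7 pairs were left against a 95th percentile of 6. That margin, in 1 of 8 sets and a test chosen afterwards, is too small to decide there. For genes higher in the yolk sac tumour line 5 were left against a 95th percentile of 6. For those higher in the embryonal carcinoma line 2 of 4 were left at a 95th percentile of 2. Removal went by related names and overlapping gene models. The histone genes H2BC4 and H2AC6 and the chemokine genes PF4 and CXCL5 were therefore still counted as pairs in these sets. For genes lower in the seminoma line 3 pairs were found in all and 1 after removal. Loss or silencing of a stretch of chromosome in the seminoma line could thus be neither excluded nor shown. Copy number or regional chromatin differences may underlie the pairs, which stays a hypothesis found and examined on the same data.

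Genes set apart downward by a single probe set could reflect failure of that probe set. Of 119 such genes with another informative probe set, 2.52% (95% exact Clopper-Pearson interval 0.523 to 7.19) had others that were not lower by at least 1 on the log2 scale, which argues against failure of single probe sets as the general cause among these 119. Genes without such a probe set were not covered. Of the genes named above as lower, these included ZIC2, BEX1, GPX1, HDHD5, BST2, EPAS1, LGALS1, NUDT19, CD9 and UBE2C. With the median over all probe sets of a gene, lower calls went from 111 to 65 in the seminoma line, from 48 to 23 in the embryonal carcinoma line and from 252 to 133 in the yolk sac tumour line. Low signal of the second probe set cannot be told apart as a reason, because the shares of 2.27% among 44 bright and 2.67% among 75 dimmer second probe sets rest on 1 and 2 genes, too few for the closeness set beforehand as counting against it to decide. A difference of subtype stays open as untested.

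In limma the real contrast of seminoma against the rest gave 0 genes at 0.05 adjusted. All 4 of the 4 ways of setting 1 line against 3 gave at least as many genes, as any must against a count of 0, and the highest other was 71. The ways are too few for a share under 0.05. The 71 genes came from setting the yolk sac tumour line apart, 67 of them lower and on values without the floor. Whether the larger count comes from a structure of the samples cannot be shown with 1 array against a spread taken from the others.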

How the results depend on the processing

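The alternatives without a floor, with a floor at the unspiked controls, with quantile normalization, scaled to the spiked-in controls, and limma on floored values or values plus the floor were chosen after the result was seen. No paired analysis was possible because each line is a different tumour and no numbers pair them. With 1 array per line, leaving out a replicate was replaced by leaving out a line. Of the values for named genes under alternatives, 696 kept their direction and their side of the threshold, 11 fell below the threshold and 0 reversed. Leaving out a line, removing or lowering the floor and changing the filter cannot narrow the margins of these genes. Much of the 696 was therefore fixed in advance and does not measure stability. Of the 11, 8 fell with the median over probe sets and 3 without _s_at and _x_at probe sets. Of list medians outside the random range, 128 stayed outside and 22 did not. That count covers leaving out a line, the median over probe sets and no filter, but not the changes of scaling. With other scalings, medians moved inside for germ cell genes in the teratoma line, cancer-testis genes in the seminoma line and endoderm genes in the embryonal carcinoma line. The filter cannot move the counts of the size rule, since genes below the floor have no margin.

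For genes higher and lower, a threshold of 1 gave 690 and 467 in the seminoma line, 420 and 295 in the teratoma line, 471 and 278 in the embryonal carcinoma line, and 726 and 664 in the yolk sac tumour line, by construction more. The mean of the other lines as reference gave 484 and 358, 309 and 208, 376 and 204, and 464 and 610 in that order. With no floor 326 genes were lower in the seminoma line, 121 higher and 198 lower in the teratoma line, 150 and 193 in the embryonal carcinoma line, and 713 lower in the yolk sac tumour line. A floor at the unspiked controls gave 66 lower genes in the teratoma line, 82 in the embryonal carcinoma line and 415 in the yolk sac tumour line. With the median over probe sets 65 genes were lower in the seminoma line (63 shared with the 111), 51 higher in the teratoma line (49 shared), 23 lower in the embryonal carcinoma line (21 shared) and 133 lower in the yolk sac tumour line (129 shared). The cause was not tested. Scaling to the spiked-in controls gave 147 higher genes in the embryonal carcinoma line, and moved the median difference of all genes to 0.27 there and to -0.31 in the yolk sac tumour line.

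Leaving out a line sets fewer others to exceed, so counts grow. Higher and lower genes ran from 301 to 361 and from 173 to 268 in the seminoma line, from 127 to 267 and from 86 to 122 in the teratoma line, from 147 to 265 and from 93 to 127 in the embryonal carcinoma line, and from 312 to 343 and from 325 to 418 in the yolk sac tumour line. Among counts that grew over 1.5 times, the seminoma line had 361 higher genes without the embryonal carcinoma line, and 173, 202 and 268 lower genes without the teratoma, embryonal carcinoma and yolk sac tumour lines. The teratoma line had 127, 267 and 146 higher and 86, 120 and 122 lower genes without the seminoma, embryonal carcinoma and yolk sac tumour lines. The embryonal carcinoma line had 193, 265 and 147 higher and 113, 127 and 93 lower genes without the seminoma, teratoma and yolk sac tumour lines. The yolk sac tumour line had 418 lower genes without the seminoma line and 384 without the teratoma line. Between 20 and 25 list medians lay outside the random range when a line was left out.

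limma called 1 gene, ZIC2, with the median over probe sets, without probe sets matching several transcripts, with the stricter filter and with centred arrays, and 0 genes under each other alternative and without each line. Over these alternatives the smallest adjusted p ran from 0.0255 to 0.889. Pairs of lines differed without a floor by 2184 genes (seminoma and teratoma), 2081 (seminoma and embryonal carcinoma), 2716 (seminoma and yolk sac tumour), 1548 (teratoma and embryonal carcinoma), 2469 (teratoma and yolk sac tumour) and 2620 (embryonal carcinoma and yolk sac tumour). A threshold of 1 gave 3904, 3678, 4072, 3104, 3819 and 4032 in that order. The teratoma and embryonal carcinoma lines differed by 457 genes with the median over probe sets, and they were the pair with the fewest under each alternative run. Signal over background limits folds in both directions. The nearest other line lay at the floor for 68 of 222 higher genes in the seminoma line, 34 of 78 in the teratoma line, 20 of 90 in the embryonal carcinoma line and 82 of 253 in the yolk sac tumour line. The line itself lay there for 36 of 111, 13 of 36, 24 of 48 and 167 of 252 lower genes.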

Other observations

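The gene families and chromosomes below were chosen after the values were seen, among 256 families of related symbols and all chromosomes. No explanation is offered for them. Of 43 histone genes 14 were higher and 0 lower in the yolk sac tumour line, with a median difference of 1.17. When scaled to the spiked-in controls 12 were higher, with a median of 0.79 where that of all genes was -0.31. Of the 14 genes 5 are read by _x_at and 2 by _s_at probe sets, which match several transcripts, and the poly-A controls of that array were shifted by 0.53 on the log2 scale. H1-2 had 24137 units there, 24.5-fold above the next line, and H2BC12 had 32510 units, 13.3-fold above. Of 8 metallothionein genes 7 were lower in that line under each scaling tried, with a median of -4.59. MT2A had 575 units and MT1X 377 units, 13.1-fold and 14.5-fold below the next line. Since 7 of the 8 are read by probe sets that match several transcripts, the members cannot be separated. The histone and metallothionein genes named here were chosen after their values were seen.

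By chromosome, the 227 genes of chromosome 18 had a median of 0.46 in the yolk sac tumour line, with 16 higher and 3 lower, and its median stayed above all random gene sets of that size at 0.07 when scaled to the spiked-in controls, where the median of all genes was -0.31. The 545 genes of chromosome 8 had a median of 0.34 in the seminoma line, with 16 higher and 3 lower, and of -0.18 in the yolk sac tumour line, with 9 higher and 26 lower. The 548 genes of chromosome X had a median of -0.38 in the seminoma line. Medians above or below all random gene sets were common in every line, so that position does not single out these chromosomes. Chromosome 14 had 0.35 in the yolk sac tumour line, and chromosome 17 had 0.34 in the embryonal carcinoma line. Chromosome 21 had -0.32 in the embryonal carcinoma line and 0.31 in the teratoma line.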
